A study of Oryza sativa Japonica Group with 12 samples.

How the data were processed

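The series holds RNA sequencing of 12 shoot samples of rice cultivar ZH11 in 4 groups of 3: wild type and osfkbp20-1b mutant, mock or 20% PEG for 6 h. Per the labels, seedlings germinated for 3 days on gel and grew for 4 days in tubes at 26 °C, with 14 h light, 10 h dark and 65% humidity, and the RNA came from leaf. The submitters' processing notes list HTSeq, DESeq and the IRGSP-1.0 build; the aligner and annotation release are not given in the sources used here. Grouping followed the sample labels alone.

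The authors deposited 2 full tables, for mock and for PEG, each with 349605 lines: 197136 exon lines and 152469 intron lines of 44667 transcripts and 37857 genes on 12 chromosomes. For each library these tables hold a normalized signal, which the authors made from the read count of the line plus 1 times one constant per library. Dividing by that constant gave whole numbers for 100% of values within 0.001, and these are called recovered reads. The added 1 was checked by fits of the scale, of which 34 of 36 favoured it. For each intron the deposited ratio is its value over the mean of its 2 flanking exons, and recomputing it gave a largest difference of 4.96e-12. The deposited p-value is two-sided and unadjusted, computed by the authors between 3 and 3 libraries. The authors also deposited 2 filtered sheets with marked introns; a p under 0.05, a 2-fold change of the mean ratio and 20 normalized reads in a library rebuild those marks exactly. Lines with equal coordinates were merged, which left 126849 introns and 175931 exons; 27264 introns overlap an annotated exon, 4696 of them one of their own gene.

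The design written before the data were examined assumed counts, but the tables held normalized values and ratios, so limma on the log2 ratio, until then listed as a second test, became the test of introns. For genes the design named edgeR's quasi-likelihood test, and limma was used there too. On the recovered reads edgeR, for introns set against the flanking exons, was run only as an alternative. Introns were kept by edgeR's filterByExpr on recovered reads, and limma 3.58.1 was fitted to the log2 deposited ratio with an intensity trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. No further pseudocount was added. Mutant and WT were compared within each table. The interaction and the 2 comparisons of PEG with mock were fitted over all 12 libraries. This is possible because the authors' constant of each library cancels in the ratio, though libraries still differ in their median ratio. For genes, recovered exon reads of the first transcript of each gene were scaled by TMM in edgeR 4.0.16 and tested by limma on log2 CPM, read counts scaled to the TMM library size, with a prior count of 1. DESeq2 1.42.0 and edgeR's quasi-likelihood test served as other tools. A fold against a group without reads is a lower bound from a floor of 3 counts over the group. Tables were handled in R 4.3.3 and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

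Camera with a preset correlation of 0.01 tested 18 gene lists fixed from the description words of the files: splicing machinery, immunophilins, abscisic acid and drought regulators, LEA and osmolyte genes, heat shock and chaperones, redox, photosynthesis, ribosomal proteins, circadian clock, transcription factors, protein kinases, ubiquitin and proteasome, aquaporins and ion transport, RNA decay and export, reference genes, root markers, dividing cell markers and reproductive tissue markers. The same lists were tested with a correlation estimated from the data. Named items followed a written rule. Among calls with a mean of at least 20 reads whose groups did not overlap, up to 8 with the largest change each way were taken. The lowest library of the higher group had to lie above the highest of the other. Where fewer than 5 introns were called, those of smallest p were taken. Up to 3 calls per list were added without asking for separation. For the interaction the numbers were 5 and 1, and no separation was asked. Separated libraries of items named for size thus follow from the rule and are no result. The gene Os01g0844300 was added by hand, outside this rule. Gene names come from the descriptions in the files, because the reference table given matched only 1 gene identifier. No description names OsFKBP20-1b, and no identifier was guessed for it.

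Depth was 25768338 to 36744649 recovered reads per library. The method was tested on simulated data with 3 against 3 libraries. Changed introns and genes were drawn only from those with a mean of at least 20 reads. Many tested introns had few reads, and recovery below that mean was not measured. Limma found 15% and 17% of introns changed by 1 on the log2 scale in mock and PEG, and 95% and 97% of those changed by 2. For genes it found 81% and 75%, and 100% at 2. Unchanged introns made up 5.98% and 7.38% of calls, and unchanged genes 4.76% and 3.31%. Camera found the changed list and called 0 of 100 unchanged lists. Simulated introns and genes were drawn independently, all with a dispersion of 0.03. The simulation therefore could not show how often camera calls lists of genes that vary together.

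The alternatives tried were other scalings, TMM scaling computed on the intron reads without the flanking exons, other filters and pseudocounts, and other tests. Settings without the flanking exons were tested per intron by edgeR, not limma, so there test and scaling changed together. Further ones were equal depth, introns free of exons, a replicate block, a stricter threshold and each library left out in turn. By the replicate numbers of the titles no pairing held: in no comparison did all pairs of the same number correlate above 0.1, so no block was used. For PEG against mock in the mutant, gene levels of replicates 1 and 2 correlated at 0.215 and 0.214. Under PEG the submitters' descriptions number the libraries otherwise, and pairing by those numbers was not tested. Group labels were also split in all 10 ways of 3 against 3, and in 100 of 200 ways for the interaction. What needs reads or a genome, such as splice junctions, was not analysed here.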

Results

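RNA was sequenced from the shoots of 1-week-old rice seedlings of the japonica cultivar ZH11, wild type (WT) or osfkbp20-1b mutant, kept under mock conditions or in 20% PEG for 6 h. PEG is a polymer that lowers the water potential of the medium and so imitates drought. The 12 libraries formed 4 groups of 3: WT mock, mutant mock, WT PEG and mutant PEG. The reads counted on exons and introns came to 28582383, 27895195 and 36744649 in the WT mock libraries, 33340569, 31633942 and 34243012 in mutant mock, 31312152, 25768338 and 31164411 in WT PEG and 29885803, 26718762 and 30567100 in mutant PEG. The retention measure was the authors' ratio of the reads of an intron to the mean of its 2 flanking exons, given here in percent. It is a ratio of reads, not of reads per base, so a long intron beside short exons can exceed 100% without being kept in every transcript. Values are means ± SD over 3 libraries (n = 3 per group), and log2 changes are limma estimates with their standard error (SE). Positions are in the IRGSP-1.0 build. No label states that replicates came from separate plants, so the p-values measure only the spread between these libraries. No deposited table names the gene OsFKBP20-1b, so its own level is not given here.

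The first comparison asked whether the mutant carried more intronic reads as a whole. In mock, 3.82% ± 0.191 of the reads of WT libraries and 4.26% ± 0.0548 of those of mutant libraries lay in introns (n = 3), a difference of 0.441 points. Under PEG the shares were 3.66% ± 0.0923 in WT and 4.07% ± 0.0420 in the mutant, a difference of 0.414 points. These shares include introns that overlap an annotated exon, so some of the reads may be exon reads. The median ratio over tested introns was 13.7% ± 1.35 in WT mock against 15.2% ± 0.259 in mutant mock. Under PEG it was 13.4% ± 0.841 in WT against 15.8% ± 0.401 in the mutant. In all 4 comparisons the lowest mutant library lay above the highest WT library; by chance groups of 3 fail to overlap, in either direction, in 10% of cases. Each two-sided exact permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. The WT mock libraries differed among themselves, with median ratios of 12.1%, 14.6% and 14.2%. Without WT mock replicate 1 the mock difference in the median ratio was 0.772 points, and without replicates 2 and 3 it was 3.08 points.

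**Figure D1:**
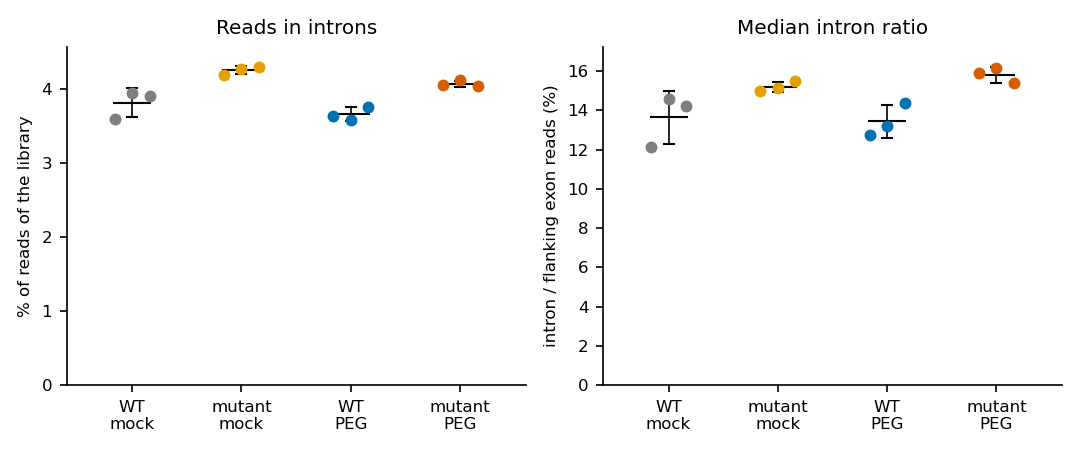
Percent of each library's reads that lay in introns, with introns overlapping an annotated exon included (left), and median intron ratio in percent (right). The 3 libraries of each group are shown, with the mean as a line and the SD as error bars. Mutant libraries lay between 4.04% and 4.30% on the left axis, and WT libraries between 3.58% and 3.95%.

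The 3 WT mock libraries also differed in a set of 13 genes on 8 chromosomes that were near silent in every WT PEG library and active in all 6 mutant libraries, a rule set after the values were seen. Os03g0299700, a conserved hypothetical protein on chromosome 3, had 6, 329 and 251 reads in WT mock, 1180, 1004 and 1109 in mutant mock, 3, 2 and 5 in WT PEG, and 936, 888 and 939 in mutant PEG. Os08g0240200 on chromosome 8 had 6, 272 and 208 reads in WT mock and 1020, 1050 and 1039 in mutant mock. As a share of the mutant mock level, the median over the 13 genes was 0.669% in WT mock replicate 1, 31.3% in replicate 2 and 19.4% in replicate 3. The same rule turned round, near silent in the mutant and active in WT PEG, found 0 genes. A gene below its level for active genes was Os01g0844300 on chromosome 1 (36253547 to 36256956), described as similar to peptidylprolyl isomerase, the enzyme class of the FK506-binding proteins. It was picked by hand, and whether it is the mutated gene is not known. It had 43, 23 and 35 reads in WT mock and 40, 48 and 49 in WT PEG, but 1, 0 and 0 in mutant mock and 1, 0 and 0 in mutant PEG. Its change was -4.82 in mock (SE 0.513, adjusted p = 0.00175) and -5.19 under PEG (SE 0.482, adjusted p = 7.40e-05). Every comparison that uses the WT mock libraries carries this difference between them.

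**Figure D2:**
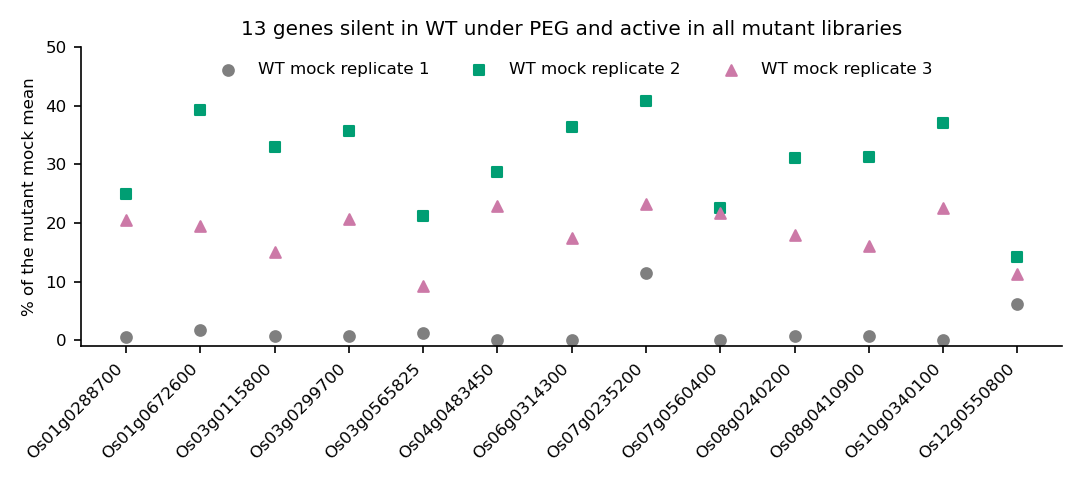
Level of the 13 genes in each WT mock library as a percent of the mean of the 3 mutant mock libraries. Replicate 2 lay between 14.2% and 40.8% and replicate 3 between 9.3% and 23.2%, while replicate 1 lay between 0% and 11.4%.

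For introns, the comparison of mutant with WT under mock conditions asked which introns the mutation altered without stress. The largest increase past the threshold was in intron 11 of 12 of Os12g0137200 (chromosome 12, 1806499 to 1806962), from a family of saccharopine dehydrogenases, enzymes of lysine breakdown. Its ratio rose from 21.5% ± 3.58 in WT to 59.7% ± 6.13 in the mutant (log2 1.48, SE 0.161, adjusted p = 0.0180). In intron 4 of Os01g0150800 (chromosome 1, 2743505 to 2745796), which encodes a PTPLA-domain protein, the ratio rose from 569% ± 75.4 to 1384% ± 189 (log2 1.28, SE 0.146, adjusted p = 0.0180). The ratio of intron 3 of Os03g0286300 (chromosome 3, 9874709 to 9876014), similar to a phosphate and phosphoenolpyruvate translocator, rose from 10.2% ± 1.03 to 20.0% ± 0.808 (log2 0.98, adjusted p = 0.0240). The only intron past the threshold in the other direction was intron 2 of Os12g0541500 (chromosome 12, 21663695 to 21664569), in a gene for chloroplast elongation factor Ts, where the ratio fell from 15.8% ± 1.77 to 8.37% ± 1.03 (log2 -0.92, SE 0.118, adjusted p = 0.0242). The remaining 4 increases were in Os02g0694201 (110.0% to 218%, log2 0.99), Os02g0200900 (14.2% to 24.1%, log2 0.76), Os01g0392600 (437% to 688%, log2 0.66) and Os04g0459500 (186% to 258%, log2 0.47, adjusted p = 0.00202). The last 3 of these and the intron of Os12g0541500 overlap an exon of another transcript of their gene. With intron reads scaled by TMM in place of the flanking exons, and tested by edgeR, the change of Os01g0392600 turned negative, -0.82.

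Limma called 7 introns higher and 1 lower of 18107 tested in mock, and 2039 introns had an unadjusted p under 0.05, 1641 of them higher. The next introns on the lower side were not past the threshold: Os10g0114850 (log2 -1.08, adjusted p = 0.0659), Os09g0248200 (log2 -0.54, adjusted p = 0.0677), Os10g0323000 (log2 -1.68, adjusted p = 0.0810) and Os06g0476200 (log2 -0.58, adjusted p = 0.0978). The median log2 change over all tested introns was 0.10. With intron reads scaled by TMM among introns in place of the flanking exons, and edgeR in place of limma, it was 0.00. There 172 introns were called higher and 179 lower. With each library's median subtracted it was -0.06, with 4 higher and 2 lower. Both settings centre the introns of each library by construction, so they can neither show nor exclude a general rise. EdgeR called 10 introns and DESeq2 75. The count depended on single libraries: it was 53 without WT mock replicate 1, 34 without replicate 2 and 2 without replicate 3, and 2, 2 and 1 without mutant mock replicates 1, 2 and 3. With WT mock replicates 2 and 3 both left out, and the lone WT mock library assumed to vary like the other groups, it was 732, 701 of them higher.

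Under PEG, mutant and WT were compared to ask which introns the mutation altered during water stress. Intron 11 of Os12g0137200 was called again, with 15.9% ± 4.61 in WT and 58.5% ± 3.85 in the mutant (log2 1.92, SE 0.209, adjusted p = 0.00316). In intron 13 of 25 of Os04g0280200 (chromosome 4, 11876103 to 11878214), a hypothetical conserved gene, the ratio rose from 15.9% ± 4.92 to 84.1% ± 5.76 (log2 2.45, SE 0.263, adjusted p = 0.00316), and this intron overlaps an exon on the other strand. The ratio of intron 15, the last, of the ABC transporter gene Os07g0464600 (chromosome 7, 16384715 to 16386549) rose from 7.96% ± 4.71 to 32.4% ± 9.08 (log2 2.13, adjusted p = 0.0453). In intron 2 of Os08g0159100, a tetraspanin, it rose from 8.57% ± 1.41 to 31.2% ± 4.72 (log2 1.86, adjusted p = 0.0234). The largest change among the named introns was 6.09 in Os04g0587451 (43.9% ± 21.1 to 2889% ± 1002, adjusted p = 1.01e-04). This intron lies within an exon of another gene on the same strand, so its reads are not separable from that gene. Of 93 introns of splicing genes 3 were called. Intron 2 of Os05g0564200 (chromosome 5, 28080432 to 28081662), the small subunit of U2AF, which recognises the end of introns, rose from 27.2% ± 5.57 to 45.6% ± 5.70 (log2 0.76, SE 0.145, adjusted p = 0.0384). Intron 6 of Os10g0115600, the U1 snRNP 70 kDa protein, rose from 228% ± 38.6 to 328% ± 21.2 (log2 0.54, adjusted p = 0.0351), where it overlaps an exon of another transcript of the gene. The intron of Os04g0385700, a splicing-factor-related gene, rose from 6.15% ± 1.75 to 16.02% ± 4.18 (log2 1.39, adjusted p = 0.0480).

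Os10g0456800 encodes a CHY zinc finger co-activator of the drought and salt tolerance factor DST. Its intron 9 of 10 (chromosome 10, 16705916 to 16705997) had the largest decrease under PEG among introns past the threshold whose groups did not overlap. Its ratio fell from 11.3% ± 2.45 in WT to 4.80% ± 0.347 in the mutant (log2 -1.22, SE 0.203, adjusted p = 0.0231), while the exon reads of the gene rose from 148 ± 4.03 to 368 ± 11.95 CPM (read counts scaled to library size; log2 1.33, adjusted p = 1.09e-06). In the only intron of Os02g0626400, phenylalanine ammonia-lyase, the entry enzyme of the phenylpropanoid pathway, the ratio fell from 1.60% ± 0.168 to 0.856% ± 0.104 (log2 -0.91, adjusted p = 0.0212). It also fell in the photosystem genes Os06g0320500 (1.27% to 0.802%, log2 -0.66) and Os03g0778100 (1.31% to 0.828%, log2 -0.66). In Os03g0670700, a glycine-rich RNA-binding protein induced by abscisic acid, 3 overlapping versions of intron 2 fell by 0.50, 0.49 and 0.33 on the log2 scale, and all 3 overlap an exon of another transcript of the gene.

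**Figure D3:**
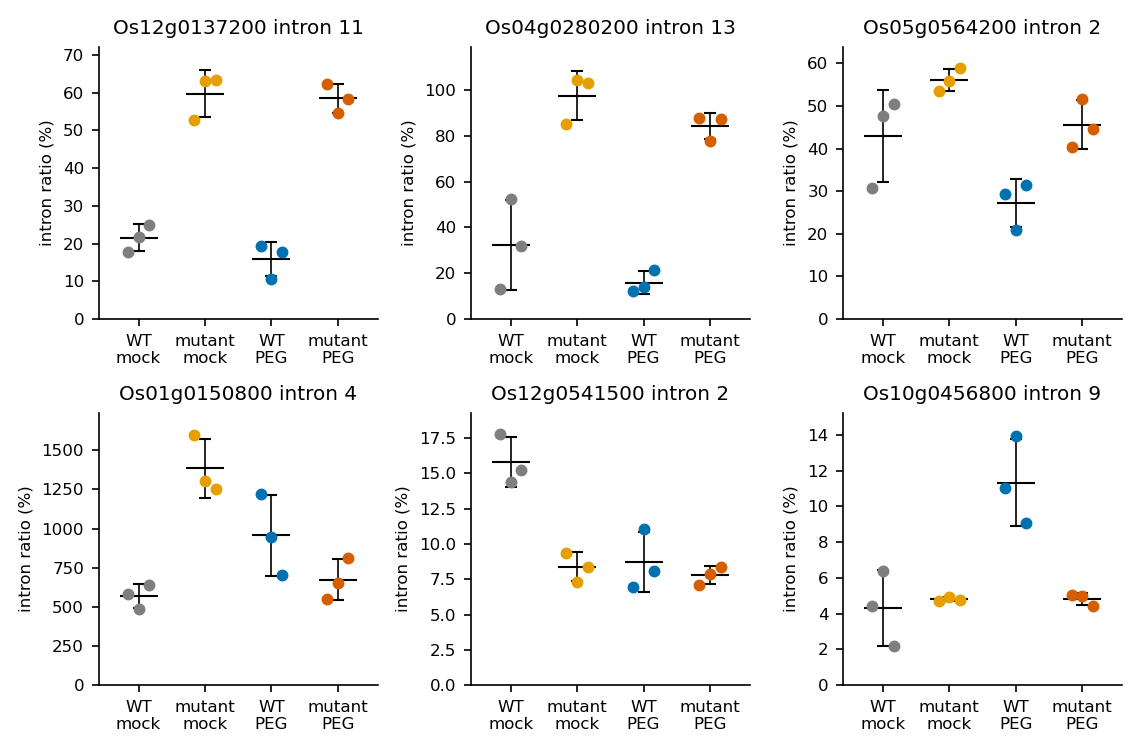
Intron ratio in percent for 6 introns in the 3 libraries of each group, with the mean as a line and the SD as error bars. Intron 11 of Os12g0137200 lay near 60% in both mutant groups and between 15.9% and 21.5% on average in both WT groups.

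Limma called 153 introns higher and 16 lower in the mutant of 16446 tested under PEG, in 164 genes, and 2474 introns had an unadjusted p under 0.05, 2058 of them higher. The median log2 change over all tested introns was 0.11. It moved to -0.02 with intron reads scaled by TMM among introns in place of the flanking exons, and edgeR in place of limma. There 616 introns were called higher and 463 lower. With each library's median subtracted it was -0.12, with 38 higher and 56 lower. Both settings centre the introns of each library by construction, so they can neither show nor exclude a general rise. EdgeR called 210 higher and 19 lower, and DESeq2 173 and 15. Of the 169 calls, 65 overlap an annotated exon. The count was 391 without WT PEG replicate 3, 91 without replicate 1 and 112 without replicate 2, and 17, 14 and 33 without mutant PEG replicates 1, 2 and 3.

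By fixed gene list, the calls under PEG were 7 higher and 1 lower among 735 introns of transcription factor genes and 3 higher and 0 lower among 93 of the splicing machinery (8 and 0 adjusted over the list alone). The 236 introns of redox genes gave 3 higher (8 adjusted over the list alone), the 356 of the ubiquitin and proteasome list 4, the 117 of the RNA decay and export list 3, the 470 of protein kinases 2 and the 103 of aquaporins and ion transport 2 (3 adjusted over the list alone). Among reproductive tissue markers 2 of 83 introns were higher (4 adjusted over the list alone), among dividing cell markers 2 of 24 (3 adjusted over the list alone), among clock genes 1 of 31 (2 adjusted over the list alone) and among heat shock and chaperone genes 1 of 167. The drought and abscisic acid list gave 3 lower, all in Os03g0670700, and photosynthesis 2 lower; adjusted over the list alone they gave 3 higher and 3 lower, and 2 and 2. Limma called 0 introns among the 72 of immunophilins (4 adjusted over the list alone), the 18 of LEA and osmolyte genes, the 312 of ribosomal proteins, the 54 of reference genes and the 15 of root markers. Some members do not do what the list name says: Os04g0250700 in the RNA decay list is of the uncharacterised family UPF0307, Os05g0558800 there is a jasmonate-signalling adaptor, and Os01g0645200 in the ion transport list is a bile acid and sodium symporter (14.9% ± 1.86 to 32.0% ± 6.75, log2 1.09). Camera, which compares a list with all other genes, gave adjusted p = 0.0635 for the splicing machinery, upward, and 0.0635 for photosynthesis, downward, so neither passed. In mock all 18 lists had adjusted p = 0.978, and 1 intron of a list was called, in Os02g0200900 of the ubiquitin list. Of 33 introns of dividing cell markers 12 were higher in mock adjusted over the list alone, but none over all introns, and the list as a whole had a median log2 of 0.01 (camera downward).

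The mock and PEG comparisons used different libraries, and 15169 introns were tested in both. Of the 153 introns called higher under PEG, 144 (94.1%) were also above 0 in mock, against 63.3% of all introns tested in both, with a median log2 change of 0.43 in mock and 0.89 under PEG. Of the 16 called lower, 10 were below 0 in mock. One intron, that of Os12g0137200, was called in both, where independent calls would give 0.0706. Across introns, which are not independent replicates, Pearson's r between the changes was 0.264 and Spearman's rho 0.255.

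**Figure D4:**
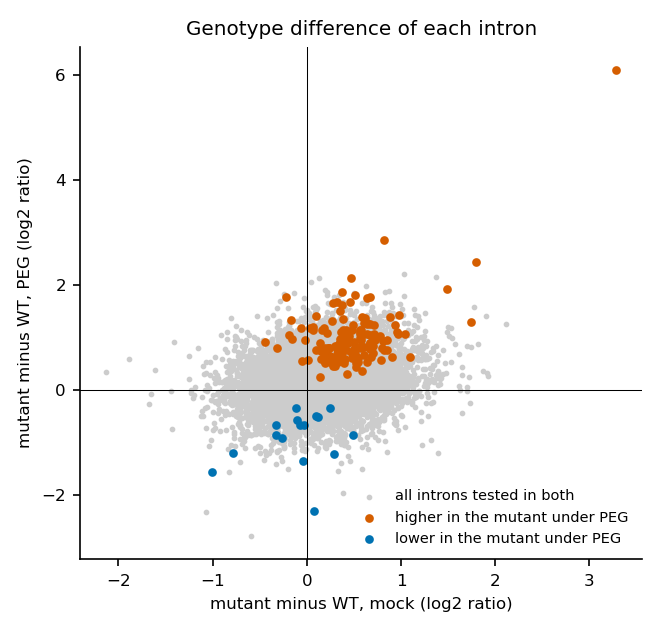
Log2 change of the intron ratio, mutant minus WT, in mock (horizontal axis) and under PEG (vertical axis) for all introns tested in both, with the 153 called higher and the 16 called lower under PEG in colour. Of the 153, 144 lie to the right of 0.

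Whether the genotype effect itself differed between PEG and mock was tested over all 12 libraries. In intron 4 of Os01g0150800 the mutant stood above WT in mock (1384% against 569%) but not under PEG (672% ± 131 against 956% ± 260), a difference of effects of -1.77 (SE 0.263, adjusted p = 0.0321). In intron 2 of Os02g0200900 the order also turned, from 24.1% against 14.2% in mock to 17.97% ± 1.78 against 21.0% ± 2.11 under PEG (log2 -0.98, SE 0.136, adjusted p = 0.0205). Intron 2 of Os09g0535000 (chromosome 9, 21035298 to 21036035), chloroplast triosephosphate isomerase, had 139% ± 6.19 in WT mock and 126% ± 18.9 in mutant mock, then 66.2% ± 6.08 in WT PEG and 130% ± 18.4 in mutant PEG (log2 1.13, SE 0.153, adjusted p = 0.0205). These last 2 introns overlap an exon of another transcript of their gene. Not past the threshold were Os07g0543000 (log2 1.245, adjusted p = 0.212), Os05g0367400 (log2 -2.59, adjusted p = 0.147) and Os06g0188550 (log2 -1.34, adjusted p = 0.204). Limma called 1 intron with a positive and 2 with a negative difference of effects (PEG minus mock) of 20829 tested, with 1405 at an unadjusted p under 0.05. EdgeR called 3 and DESeq2 4. In edgeR with TMM among introns in place of the flanking exons there were 30 positive and 16 negative. The count was 9 without WT mock replicate 1. It was 0 in limma when WT mock replicate 2 or 3, mutant mock replicate 1 or 3, WT PEG replicate 1, or mutant PEG replicate 2 or 3 was left out. With WT mock replicates 2 and 3 both out it was 25, 21 of them negative. The introns of the splicing machinery shifted upward against other genes (median log2 0.16, camera adjusted p = 0.0277), but adjusted p = 0.385 with an estimated correlation.

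PEG against mock within WT asked what water stress did to introns in normal plants. The ratio rose in intron 4 of Os03g0132200 (chromosome 3, 1832476 to 1832564), an expansin-like protein of cell wall loosening, from 2.43% ± 0.254 to 6.80% ± 0.371 (log2 1.49, SE 0.157, adjusted p = 2.17e-04). It rose in intron 4 of the homeodomain gene Os03g0764600 from 1.56% ± 0.165 to 5.27% ± 0.193 (log2 1.76, adjusted p = 0.00894). It fell in intron 4 of Os01g0563000 (chromosome 1, 21424791 to 21425449) from 13.2% ± 1.63 to 4.18% ± 0.835 (log2 -1.67, SE 0.175, adjusted p = 2.17e-04). It fell in intron 1 of Os02g0744900, geranylgeranyl reductase of chlorophyll synthesis, from 3.77% ± 1.20 to 1.12% ± 0.233 (log2 -1.72, adjusted p = 0.00283). GIGANTEA (Os01g0182600), a clock protein, fell in 2 versions of intron 2, from 12.5% ± 2.36 to 6.86% ± 0.736 (log2 -0.85, adjusted p = 0.0379) and from 16.2% ± 3.13 to 9.56% ± 1.45 (log2 -0.76, adjusted p = 0.0420). The second version overlaps an exon of another transcript, as does the intron of Os01g0563000, and the introns of Os03g0132200 and Os02g0744900 overlap an exon on the other strand. The clock regulator Os09g0532400 fell in intron 4 from 31.1% ± 3.93 to 20.1% ± 3.05 (log2 -0.63, adjusted p = 0.0357), and the SR splicing factor gene Os04g0118900 in intron 2 from 108% ± 10.8 to 61.4% ± 4.73 (log2 -0.81, adjusted p = 0.0475).

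Limma called 49 introns higher and 120 lower under PEG in WT of 20829 tested, with 2658 at an unadjusted p under 0.05. This direction depended on the scaling and on the WT mock libraries. With TMM among introns in place of the flanking exons, and edgeR in place of limma, 468 were higher and 396 lower. With each library's median subtracted there were 124 and 78 (median log2 0.09 in place of -0.07). Both settings centre the introns of each library and so set this balance themselves. They cannot show whether introns fell as a whole. Leaving out WT mock replicates 2 and 3 also turned the direction, but it left a lone WT mock library. The count was 317 without WT mock replicate 1, 57 without replicate 2 and 43 without replicate 3, and 71 and 110 without WT PEG replicates 1 and 2. The clock list shifted downward (camera adjusted p = 0.0454, 3 introns lower, 7 adjusted over the list alone), but adjusted p = 0.54 with an estimated correlation and 0.197 without WT mock replicates 2 and 3.

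In the mutant, PEG against mock gave fewer calls. The ratio fell in intron 1 of Os11g0116300 (chromosome 11, 730772 to 732632), a chalcone isomerase of flavonoid synthesis, from 72.4% ± 9.51 to 36.6% ± 7.205 (log2 -0.995, SE 0.133, adjusted p = 0.00844). It fell in intron 3 of Os01g0639900, a carbonic anhydrase, from 7.83% ± 0.778 to 4.30% ± 0.909 (log2 -0.88, adjusted p = 0.0425), and in intron 7 of the LAMMER kinase Os12g0460800 from 38.5% ± 0.373 to 25.8% ± 2.55 (log2 -0.58, adjusted p = 0.0425). It rose in intron 13 of Os09g0436500 from 18.6% ± 1.27 to 40.4% ± 9.83 (log2 1.09, SE 0.170, adjusted p = 0.0279) and in intron 1 of Os10g0409400, a polygalacturonase subunit, from 3.49% ± 0.476 to 7.24% ± 1.08 (log2 1.052, adjusted p = 0.0425). Limma called 4 introns higher and 13 lower of 20829, with 1523 at an unadjusted p under 0.05. In edgeR with TMM among introns there were 208 higher and 186 lower, and in limma with medians subtracted 7 and 6. These settings themselves centre the introns. DESeq2 called 46 in all. The count was 48 without WT mock replicate 1 and 7 without replicate 3. It was 3, 1 and 4 without mutant mock replicates 1, 2 and 3, and 6, 0 and 5 without mutant PEG replicates 1, 2 and 3, where limma's 0 calls came with 1509 introns at an unadjusted p under 0.05. The clock list was again lower (camera adjusted p = 0.0349), but adjusted p = 0.75 with an estimated correlation.

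The authors' own list of retained introns held 97 introns in mock, 81 higher and 16 lower in the mutant, and 237 under PEG, 215 higher and 22 lower. All are introns with the authors' p under 0.05, a mean ratio at least 2-fold apart and at least 20 normalized reads in a library. Of the 96 and 235 that could be tested here, limma called 2 in mock and 61 under PEG. All had the same sign, which was nearly set in advance, because limma used the same ratios of the same libraries. Adjusted over all introns by Benjamini-Hochberg, 0 of the marked introns kept an adjusted value under 0.05 in either list, while 23 other introns did in mock and 29 under PEG. The introns of Os12g0137200 and Os01g0150800 were the 2 in mock.

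Exon reads per gene gave the expression changes beside these. In mock, the mutant had more reads of Os03g0815100, a relative of the stress factor OsNAC6, with 50.6 CPM ± 3.88 against 25.4 ± 0.392 (log2 0.98, SE 0.0905, adjusted p = 9.99e-04). The proline synthesis gene Os05g0455500 stood at 125 CPM ± 12.9 against 86.5 ± 7.93 (log2 0.52, adjusted p = 0.0206), and the kinase gene Os11g0213000 at 43.0 CPM ± 8.78 against 9.55 ± 4.14 (log2 2.24, adjusted p = 0.00349). Lower in the mutant were Os02g0766700, a bZIP factor of abscisic acid signalling (17.4 CPM ± 1.06 against 22.7 ± 0.375, log2 -0.39, adjusted p = 0.0440), and the aquaporin gene Os07g0448800 (455 CPM ± 42.4 against 660.0 ± 11.8, log2 -0.55, adjusted p = 0.0108). The metallothionein-like gene Os05g0202800 had 0.0674 CPM ± 0.0607 against 17.9 ± 16.1 (log2 -6.20, adjusted p = 0.0236), with an SD in WT close to its mean. Limma called 793 genes higher and 538 lower of 23316. The count was 196 without WT mock replicate 3, 657, 404 and 83 without mutant mock replicates 1, 2 and 3, and DESeq2 called 2104. Of the reference genes on the fixed list, ubiquitin Os01g0328400 was lower in the mutant (log2 -0.37, adjusted p = 0.0352) and actin Os03g0718100 did not pass (log2 -0.32, adjusted p = 0.0834).

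Under PEG single water-stress genes were lower in the mutant. Of the 44 genes of the LEA and osmolyte list, which holds galactinol synthase and raffinose synthase, 4 were higher and 11 lower (6 and 14 adjusted over the list alone, camera adjusted p = 0.0434, downward), but adjusted p = 0.34 with an estimated correlation. Of 88 drought and abscisic acid regulators 15 were higher and 7 lower (19 and 8 adjusted over the list alone, camera adjusted p = 0.213, upward). Galactinol synthase Os03g0316200, which opens the raffinose sugar pathway, stood at 11.9 CPM ± 0.532 in the mutant against 42.6 ± 15.5 in WT (log2 -1.76, SE 0.218, adjusted p = 5.20e-04). The dehydrin gene RAB21 (Os11g0454300) stood at 7.29 CPM ± 3.22 against 19.4 ± 8.20 (log2 -1.38, SE 0.346, adjusted p = 0.0223), and a second dehydrin, Os11g0451700, at 0.117 CPM ± 0.133 against 1.52 ± 0.473 (log2 -3.62, adjusted p = 0.00437). A raffinose synthase, Os01g0170000, was at 4.85 CPM ± 0.700 against 11.5 ± 2.18 (log2 -1.21, adjusted p = 0.00127), and the potassium transporter Os09g0448200 at 3.71 CPM ± 0.0428 against 11.1 ± 1.74 (log2 -1.55, adjusted p = 1.34e-04). Higher in the mutant were Os03g0815100 (50.7 CPM ± 4.27 against 23.8 ± 1.40, log2 1.10, adjusted p = 4.13e-05), trehalose-6-phosphate synthase Os08g0414700 (20.9 ± 2.20 against 7.21 ± 1.89, log2 1.57), the abiotic stress kinase Os11g0113700 (195 ± 8.12 against 54.1 ± 1.43, log2 1.86) and the calcium-sensor-linked kinase Os12g0113500 (199 ± 13.1 against 63.1 ± 3.03, log2 1.67). Of 67 splicing machinery genes 13 were higher and 3 lower, and the list did not pass (camera adjusted p = 0.213). Among the higher were the SR gene Os02g0122800 at 302 CPM ± 3.58 against 189 ± 5.69 (log2 0.69, adjusted p = 8.48e-05) and SC35 (Os08g0486200) at 182 ± 5.40 against 118 ± 8.56 (log2 0.64, adjusted p = 3.48e-04). Of 72 photosynthesis genes 4 were higher and 22 lower (camera adjusted p = 0.00458), but adjusted p = 0.327 with an estimated correlation. One of the lower was PsbS (Os01g0869800), which dissipates excess light (589.8 CPM ± 46.0 against 908 ± 26.7, log2 -0.61, adjusted p = 5.55e-04).

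Limma called 2019 genes higher and 1579 lower under PEG of 23279, and DESeq2 3847 in all. The count was 2038 without WT PEG replicate 3 and 1623 without mutant PEG replicate 3. Some genes had no read in a group: Os03g0565825 had 0 reads in WT PEG and 861 in mutant PEG, at least 291-fold higher, and Os04g0483450 had 0 and 804, at least 271-fold higher, both against a floor of 3 counts over the group. Between mock and PEG, 379 genes were called higher in the mutant in both comparisons and 241 lower in both, against 69.4 and 36.1 for independent calls, and 4 in opposite directions.

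The genotype effect on expression differed between treatments for 160 genes by limma of 24007, with a positive difference (PEG minus mock) in 111 and a negative one in 49. For galactinol synthase Os03g0316200, 14.9 CPM ± 0.934 in mutant mock and 16.7 ± 1.45 in WT mock turned into the gap under PEG (log2 -1.61, SE 0.272, adjusted p = 0.0101). For RAB21 the difference of effects was -1.69 (SE 0.576, adjusted p = 0.193) and did not pass. The kinase Os11g0113700 had a positive difference (log2 0.96, adjusted p = 0.00456), as had the drought-related MYB factor Os01g0975300 (log2 0.91, adjusted p = 0.00675) and the SR gene Os02g0122800 (log2 0.43, adjusted p = 0.0405). The potassium transporter Os06g0270200 had a negative one (log2 -0.94, adjusted p = 0.00779). The count was 249, 284 and 80 without WT mock replicates 1, 2 and 3, 74 and 71 without mutant mock replicates 1 and 3, 97 without WT PEG replicate 1 and 75 without mutant PEG replicate 3. Without both WT mock replicates 2 and 3 it was 574, and DESeq2 called 653.

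PEG against mock within WT raised RAB21 from 0.602 CPM ± 0.168 to 19.4 ± 8.20 (log2 4.84, SE 0.407, adjusted p = 1.62e-06), and within the mutant from 0.802 ± 0.371 to 7.29 ± 3.22 (log2 3.15, SE 0.407, adjusted p = 2.01e-04). The phosphatase 2C gene Os06g0698300, of a family that holds back abscisic acid signalling, rose from 4.88 CPM ± 0.437 to 33.4 ± 3.67 in WT (log2 2.76, adjusted p = 6.89e-08) and from 3.66 ± 0.470 to 16.4 ± 3.85 in the mutant (log2 2.13, adjusted p = 2.84e-06). Betaine aldehyde dehydrogenase Os08g0424500 rose in WT from 117 CPM ± 4.01 to 192 ± 1.07 (log2 0.71, adjusted p = 5.25e-06). The Rubisco small subunit gene Os02g0152400 fell from 619.7 CPM ± 8.11 to 203 ± 5.18 in WT (log2 -1.62, adjusted p = 5.61e-08) and from 517 ± 7.23 to 229.8 ± 33.4 in the mutant (log2 -1.18, adjusted p = 2.84e-06). Histone H2A gene Os08g0427700 fell in both, by 1.10 and 1.37 on the log2 scale. In the mutant the WRKY repressors Os09g0417600 (log2 -3.38, adjusted p = 4.17e-04) and Os09g0417800 (log2 -3.25, adjusted p = 0.00287) fell as well. Limma called 2194 genes higher and 2104 lower in WT and 1417 and 1488 in the mutant, of 24007. In WT the count was 2752 without WT mock replicate 3, 2842 without WT PEG replicate 1 and 2396 without WT mock replicates 2 and 3. In the mutant it was 1460 and 1390 without mutant mock replicates 1 and 3, and 1850 and 1455 without mutant PEG replicates 2 and 3.

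**Figure D5:**
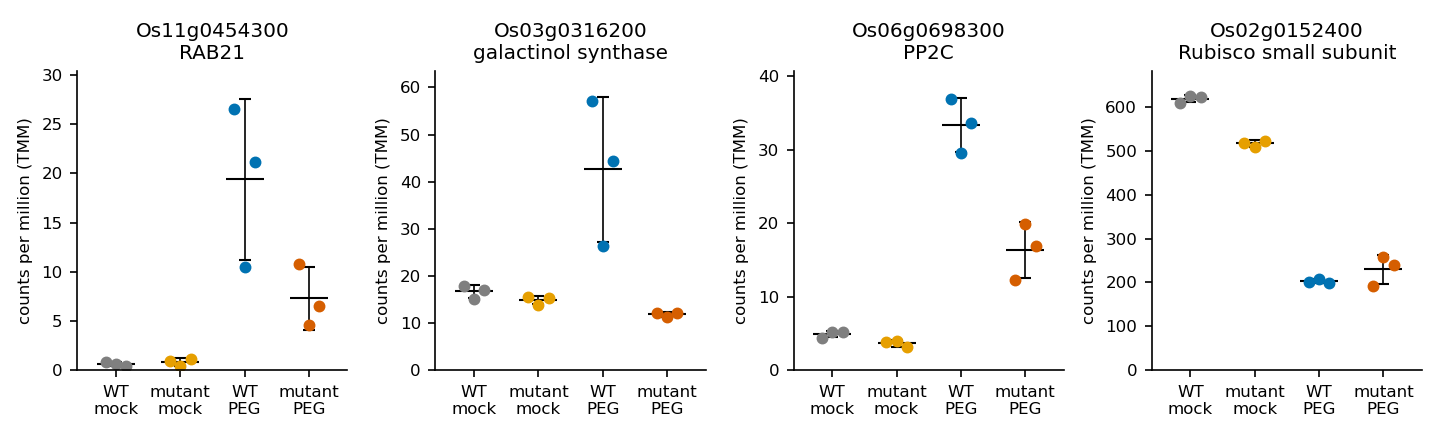
CPM of 4 genes in the 3 libraries of each group, with the mean as a line and the SD as error bars. Os11g0454300 (RAB21), Os03g0316200 and Os06g0698300 had higher means in WT PEG than in mutant PEG, and Os02g0152400 was lower under PEG than in mock in both genotypes.

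By list, gene expression in the mutant under PEG was lower for ribosomal proteins (camera adjusted p = 1.03e-04, 8 higher and 22 lower of 329, 4 and 1 adjusted over the list alone), but adjusted p = 0.561 with an estimated correlation. It was lower for photosynthesis (0.00458, 4 and 22 of 72, 9 and 29 adjusted over the list alone), but adjusted p = 0.327 with an estimated correlation. For immunophilins (0.0115, 1 and 11 of 50, 3 and 13 adjusted over the list alone) it was adjusted p = 0.244 with an estimated correlation, and for LEA and osmolyte genes (0.0434, 4 and 11 of 44, 6 and 14 adjusted over the list alone) it was adjusted p = 0.34 with an estimated correlation. Clock genes were higher (0.00948, 7 and 0 of 17, the same counts adjusted over the list alone), among them ELF3 (Os06g0142600, log2 0.58) and GIGANTEA (log2 0.29), but adjusted p = 0.517 with an estimated correlation. In mock the lower lists were ribosomal proteins (1.04e-11, 1 and 18 of 330, 1 and 38 adjusted over the list alone), redox (0.0147, 2 and 7 of 196), immunophilins (0.0498, 0 and 3 of 49) and photosynthesis (0.0498, 1 and 1 of 72), and the higher ones clock genes (9.65e-04, 1 and 0 of 16, 6 and 0 adjusted over the list alone) and protein kinases (0.00846, 41 and 6 of 692). None of these 6 held, with adjusted p = 0.465 with an estimated correlation for ribosomal proteins, immunophilins, clock genes and kinases, 0.327 for redox and 0.707 for photosynthesis. Without WT mock replicates 2 and 3 clock genes missed the threshold in mock (camera adjusted p = 0.165), and photosynthesis had adjusted p = 3.63e-12. One called clock member in mock, Os05g0151400, is an AIG1-domain gene, and one in the ribosomal list, Os04g0608100 (log2 0.55 in mock, 1.04 under PEG), only carries a ribosomal S5 fold. In WT, PEG raised LEA and osmolyte genes (0.00117, 15 and 3 of 45), but adjusted p = 0.176 with an estimated correlation. It lowered ribosomal proteins (0.00117; 0.752 with an estimated correlation), dividing cell markers (0.00117, 1 and 8 of 29; 0.567 with an estimated correlation) and photosynthesis (0.0316, 2 and 9 of 73; 0.752 with an estimated correlation). In the mutant, PEG lowered photosynthesis (0.00341, 2 and 20 of 73; 0.658 with an estimated correlation), dividing cell markers (0.00341, 1 and 10 of 29; 0.658 with an estimated correlation) and ribosomal proteins (0.0423, 12 and 9 of 332; 0.702 with an estimated correlation). No list passed for the difference of the genotype effects on genes, where LEA and osmolyte genes and the splicing machinery had adjusted p = 0.0572 each, with 0 and 2 and with 1 and 0 genes called by limma. Without WT mock replicates 2 and 3 the splicing machinery (0.00182) and photosynthesis (0.00122) passed upward and protein kinases (0.00935) downward, a setting not run with an estimated correlation.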

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

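In this part the sorting of splits by which genotypes they kept apart was a test chosen only after seeing results, as were fits without WT mock replicates 2 and 3, and the verdict on chance was changed after the values were seen. The results here were singled out because the effect of the mutation differed between mock and PEG by a test of that difference. It passed for 3 introns: intron 4 of Os01g0150800 (log2 -1.77), intron 2 of Os02g0200900 (-0.98) and intron 2 of Os09g0535000 (1.13). It passed for 160 genes by limma. The largest were Os03g0565825 (4.48), Os12g0550800 (4.07), Os03g0826900 (3.65), the flowering-signal relative Os04g0488400 (3.50) and Os12g0113600 (3.19) among positive differences. Among negative ones they were Os02g0571100 (-6.66), Os06g0581500 (-4.44), Os03g0254200 (-3.42), Os11g0687200 (-2.98) and Os01g0130200 (-1.997). Os03g0565825 had no read in WT PEG and Os02g0571100 none in WT mock, so their sizes depend on the prior count. Os03g0565825 and Os12g0550800 belong to the 13 genes partly on in WT mock replicates 2 and 3, and without those libraries they had 2.37 (adjusted p = 0.0321) and 3.45 (adjusted p = 0.0215). Of the other 8, Os04g0488400 then missed the threshold (3.77, adjusted p = 0.0555). From the fixed lists came the SR gene Os02g0122800 (0.43), galactinol synthase Os03g0316200 (-1.61), Os02g0693200 (0.68), superoxide dismutase Os03g0219200 (0.60), the MYB factor Os01g0975300 (0.91), the kinase Os11g0113700 (0.96), Os10g0127900 (1.89) and the potassium transporter Os06g0270200 (-0.94). Among lists, the introns of the splicing machinery passed (camera adjusted p = 0.0277), but adjusted p = 0.385 with an estimated correlation.

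The labels were also split in other ways. For introns 3 of 100 splits gave at least the 3 real calls, the highest other 10, and for genes 10 of 100 gave at least the 160 real calls, the highest other 1438. The other splits with as many calls, 2 for introns and 9 for genes, kept the genotypes of 1 treatment apart and so carried the genotype effect, a structure of the samples. The 77 splits that mixed genotypes in both treatments gave 0 calls in limma, but there the genotype effect adds to the spread between libraries. By the bound of 5% of splits set beforehand, chance was excluded for introns and not for genes. That verdict was withdrawn because of this structure, and the splits are taken to decide neither count.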

How the results depend on the processing

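Tests chosen only after seeing the data were, as alternatives, edgeR set against the flanking exons and edgeR on genes. So were introns free of exons, flanking exons of at least 20 reads, subtracted medians and thinned reads. The same holds for WT mock replicates 2 and 3 left out. It also holds for an adjusted p under 0.01 for the interaction and for PEG in WT and in the mutant. Unless stated, the cause was not tested. At the depth and number of these libraries limma found 15% and 17% of simulated intron changes of 1 on the log2 scale in mock and PEG. These were in introns with a mean of at least 20 reads. Which of depth and number sets the recovery was not tested. Over named items and alternatives, genes kept direction and side of the threshold in 3965 cases, were weaker in 385 and reversed in 0. Introns kept them in 1929, were weaker in 886, stronger in 28 and reversed in 21. Lists kept them in 30 and were weaker in 30. Most items were named because they were called here, and those named for size because their groups did not overlap. Leaving out 1 library can hardly reverse these, so the tally is no independent test.

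Limma called 8 introns in mock, 169 under PEG, 3 for the interaction, 169 for PEG in WT and 17 for PEG in the mutant. By edgeR with TMM and no flanking exons the counts were 351, 1079, 46, 864 and 394. With size factors of the DESeq2 kind, also in edgeR, they were 333, 1079, 46, 858 and 386. Test and scaling changed together here, so the effect of scaling alone is not shown. The setting without the flanking exons, by its construction, also measures changes of the gene itself and centres the introns of each library. It reversed Os01g0392600 in mock (-0.82 and -0.82) and, with size factors, Os04g0459500 (-0.0036); under PEG Os07g0120900 (-0.14 and -0.14), Os05g0491200 (0.23 and 0.23) and Os07g0448800 (-0.13 and -0.13); in the interaction Os02g0813000 (-0.28 and -0.27); for PEG in WT Os10g0409400 (-0.67 and -0.68), Os02g0152400 (-0.77 and -0.78) and Os01g0689900 (0.0273 and 0.0227); for PEG in the mutant Os07g0558300 (-0.0106 and -0.00486) and Os01g0150800 (0.43 and 0.44).

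With no filter the 5 counts were 0, 0, 0, 22 and 3 in limma, with 8057, 7603 and 6992 introns at an unadjusted p under 0.05 for the first 3, where edgeR called 10, 229 and 3 with the filter. At an adjusted p under 0.01 they were 1, 12, 0, 36 and 3 (1405 unadjusted for the interaction). DESeq2 called 75 in mock and 46 for PEG in the mutant. Fisher's test on pooled reads, which ignores the spread between libraries, called 1076 in mock and 1381 under PEG. Introns free of exons gave 4 in mock, 1 for the interaction and 9 for PEG in the mutant. Thinned reads gave 18 in mock and 177 under PEG, all 12 libraries 42, flanking exons of at least 20 reads 254 under PEG, subtracted medians 94 under PEG, and a pseudocount of 0.1 times the median ratio 11 for PEG in the mutant. Without WT mock replicates 2 and 3, the lone library assumed to vary like the other groups, introns were 732 in mock and 25 for the interaction, genes 574 for the interaction and 2396 for PEG in WT, and the mock differences 3.08 points in the median ratio and 0.660 in the intron share. DESeq2 called 2104 genes in mock and 653 for the interaction.

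The replicate block gave 15 introns in mock, 67 under PEG and 10 for PEG in the mutant, 168 genes in mock, 1 list of genes for the interaction, and 0 lists of introns for PEG in WT and in the mutant by camera. The replicate numbers of the titles did not pair samples throughout, the highest correlation within a number being 0.215. Pairing by the submitters' other numbers was not tested.

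Camera's counts of lists by introns, 0, 0, 1, 1 and 1, and by genes, 6, 5, 0, 4 and 3, were all 0 with an estimated correlation. By the first intron of each gene they were 0 for the interaction and for PEG in WT and in the mutant. With no flanking exons they were 2 in mock, 3 under PEG and 0 for PEG in WT. Without WT mock replicates 2 and 3 they were 0 for introns for PEG in WT, and for genes 5 in mock, 3 for the interaction and 6 for PEG in WT. The authors' lists of 97 and 237 introns kept 27 and 61 at the authors' p under 0.01 and 0 and 0 after Benjamini-Hochberg adjustment.

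With 1 library left out, introns ranged from 1 to 53 in mock, 14 to 391 under PEG, 0 to 9 for the interaction, 43 to 317 for PEG in WT and 0 to 48 for PEG in the mutant. Genes ranged from 83 to 1424, 1623 to 3963, 71 to 284, 2752 to 4592 and 1390 to 3486. The difference in the median ratio ranged from 0.772 to 2.02 points in mock and 2.03 to 2.84 under PEG, and that in the intron share from 0.332 to 0.508 and 0.374 to 0.465.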

Other observations

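In this part the test of seedlings of the WT stock, the rule for on/off genes and the tests with subtracted medians, thinned reads, further genes far higher in the mutant and a mix were chosen only after seeing results, and the verdicts on mutant material and on a uniform rise were changed after their values were seen. The tests on introns called higher in the mutant under PEG were of length and place. Their median length was 1367 bp, against 497 bp ± 86.3 for tested introns matched on reads, and of the 131 in transcripts with at least 2 introns, 46 (35.1%) were the last intron, against 27.4% ± 3.8 for matched introns of such transcripts. Both differences went the way predicted (two-sided permutation p = 1e-04 for length and 0.044 for place, unadjusted), so longer and last introns may be affected more. The draws took introns as independent and matched them on reads alone. Of the 169 calls under PEG 65 overlap an annotated exon, and length was not separated from such overlap.

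The first pattern weighed was the excess of higher introns in the mutant under PEG. Genomic DNA in the mutant libraries was excluded: the excess of reads in introns of silent genes was 1.683% ± 0.972 of that over all introns. Unequal depth was excluded too, since 91% of calls were higher after thinning to the smallest library. A uniform rise of the intron share of each mutant library stayed open: 40.4% of calls were higher once each library's median was subtracted, which met the bound of under 60% set beforehand, but that subtraction itself sets the balance near 0, so the value decides nothing. A general effect of the mutation on splicing, the biological explanation, was not tested apart from such a rise.

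The second pattern was the set of 13 genes, near silent in WT PEG, that were partly on in WT mock replicates 2 and 3, and material of the mutant line in those libraries stayed open. Over 715 other genes their median position between WT PEG and mutant PEG was -0.0773 from that of replicate 1, 0.127 below the bound of 0.05 set beforehand, with a spread of 0.0302 over genes or 0.0958 between the 3 mutant mock libraries, and by that test alone such material was at first excluded. The bound rested on 1 reference library, and other values went the other way: 11 further genes at least 8-fold higher in the mutant than in WT PEG stood at 8.82%, 31.6% and 21.8% of the mutant mock level in the 3 libraries, and 26 at least 4-fold higher at 20%, 35.6% and 31.8%. The median ratio and intron share of replicates 2 and 3 were higher than in replicate 1, by 2.31 points and 0.327. A mix at the mean share of 25.4% would give rises of 0.782 and 0.167. The direction is that of a mix but the size is larger, and there is 1 reference library, so these values decide nothing. Seedlings of the WT stock with active copies of these genes stayed open too, with a 2.87-fold range of shares in replicate 2, and the 2 cannot be told apart.

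The third pattern was the set of 171 genes at least 4-fold apart between mutant and WT under PEG. Tracts of another genetic background in one line were weighed as a source. Pairs of such genes within 1 Mb were 0.841 times as many as among random tested genes, with a spread of 0.115. This met the bound set beforehand and speaks against tracts that hold most of these genes. Random genes already gave 91.6 pairs on average, against 77 here. A few tracts need not raise that count, and differences scattered over the genome would not, so a background difference stayed open.

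For the other comparisons the 10 possible splits of 3 against 3 libraries are too few for a share under 0.05, and in each 1 split, the real one, gave as many calls. The real and the highest other counts of introns were 8 and 0 in mock, 169 and 0 under PEG, 169 and 90 for PEG in WT, and 17 and 1 for PEG in the mutant. For genes they were 1331 and 1, 3598 and 0, 4298 and 1, and 2905 and 6.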
